A study of Mus musculus with 12 samples.

How the data were processed

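Gene expression was measured in myocardium of 12 mice in 3 groups, with 4 mice and 4 arrays in each group per the labels and the series design. The values are log2 expression values that the authors deposited as 1 table, made by robust multi-array average (RMA, which corrects background, sets the arrays to a common distribution and summarises the probes of each probe set) per the submitters' processing notes. The version of that software and the annotation it used are not given in the sources used here. Labelled RNA was prepared from 6 µg of total RNA per the labels. No earlier step was repeated, so an effect of background correction or of the RMA scaling on the values was open to checks only through a new scaling of the deposited values.

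The table held 29129 probe sets. Of these, 19572 had 1 gene symbol in the platform annotation and 0 had several, while 2634 gene probe sets had no gene name here and 6923 were control probe sets. All 19572 named probe sets matched the reference gene table (GRCm38.p6) by gene ID, and 0 symbols changed. For the 55 symbols with several probe sets, the probe set with the highest mean over all arrays was used, which left 19505 genes. Some items fixed for the report are not reported here.

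The arrays give no read depth, and their number limits the precision. The background was described with 246 reporter control probe sets, whose values had a median of 2.66 and a 95th percentile of 4.96 on the log2 scale. A gene at or below that percentile on all 4 arrays of a group is called not above background there. A fold, where given for it, is then a lower bound, from the mean of the other group against the mean of the dim group with lower values set to that percentile, and no fold is given where neither group was above it. That percentile comes from other probes, and genes below it can still differ between groups. These bounds were added after seeing the data.

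The comparisons were DM against NC, DM_AngIV against DM and DM_AngIV against NC. Each was a contrast of 1 linear model with a mean per group over all 12 arrays, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with two-sided moderated tests. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 over all genes. All 3 comparisons share arrays, and p-values measure the spread between mice of these groups. The test, the groups, the gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The named genes were, per comparison, the 6 largest rises and the 6 largest falls among called genes whose groups did not overlap, leaving out predicted genes, then the 2 members with the smallest unadjusted p in each process list, and 11 genes named whatever their values, of which 9 were analysed here. Members of lists without a call were left out of the text except where they stood in another part of the rule or passed over all genes. Further genes are named where they complete a count.

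In total 37 gene lists were fixed, 22 of processes and 15 of cell type or tissue markers, with 731 members, of which 661 were measured. The 35 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists. Each was also tested with camera at a correlation estimated per list and with fry. Members were counted as called over all genes and as called with p-values adjusted over the list alone.

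To ask whether treatment moved genes against the change in DM, the covariance across genes of the log2 fold changes was computed with the 4 DM arrays split so that the comparisons shared no array. It was averaged over the 6 ordered splits and tested with a two-sided exact permutation of the labels of the DM and DM_AngIV arrays.

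On simulated data for DM against NC, made from the means and residual spread of the 19505 genes with 200 genes changed in each of 10 runs, the test recovered 38.8% of genes changed by 0.5 on the log2 scale, 89.9% of those changed by 1 and 99.2% of those changed by 2, and 4.95% of the called genes were false. The simulated genes varied independently of each other. With 200 changed genes the adjusted threshold is also easier to pass than where few genes change. These shares can therefore be too high for the real comparisons. Alternatives covered the threshold, the filter on dim genes, the arrays in the fit, the replicate block, the probe set rule, further scaling, array weights, the prior of the variance, the list test and each array left out in turn. Alternatives with the mean of atrial marker genes as a covariate, and without the arrays with atrial marker signal (Myl7 above that 95th percentile), were added after seeing the data. The omission leaves NC replicates 2 and 4, DM replicate 3 and all 4 DM_AngIV arrays, so it also lowers the power to call genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.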

Results

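The hearts of 12 mice were profiled on single-colour expression arrays. NC mice had received injections of the vehicle for 5 days. DM mice had received streptozotocin, a toxin of the insulin-producing beta cells, for 5 days, and were kept when fasting glucose was at least 16.7 mM 2 weeks later. DM_AngIV mice were made diabetic in the same way and were infused with angiotensin IV, a fragment of angiotensin II, at 2.88 mg/kg/day from week 8 to week 24. Myocardium was taken at 6 months. The study asked how angiotensin IV acts on diabetic heart disease, with the transcription factor FoxO1, autophagy, apoptosis and fibrosis as its themes. Each group held 4 mice. Array medians lay between 4.12 and 4.19 on the log2 scale. Between 38.9% and 45.6% of genes were above the 95th percentile of the reporter control probe sets of the same array, which lay between 4.82 and 5.17. Pairs of arrays correlated across genes with r between 0.975 and 0.987.

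Transcripts of atrial muscle differed between arrays. Myl7, the atrial myosin regulatory light chain, was above the background percentile of 4.96 in NC replicates 1 and 3, at 10.08 and 7.90, and in DM replicates 1, 2 and 4, at 8.86, 9.68 and 8.10. In the other 7 arrays, with all 4 DM_AngIV arrays among them, it lay between 3.53 and 4.28. The mean of the 7 atrial cardiomyocyte markers was 6.41 ± 1.33 in NC, 6.61 ± 1.25 in DM and 5.27 ± 0.14 in DM_AngIV (SD, n = 4 each). The signal rests on part of this list. Sln and Myl4 were also highest in the arrays with Myl7 above background, but Bmp10 lay between 2.28 and 3.18 in all arrays, below that percentile. Nppa, also 1 of the 7 markers, was not lower in DM_AngIV than in DM.

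**Figure D1:**
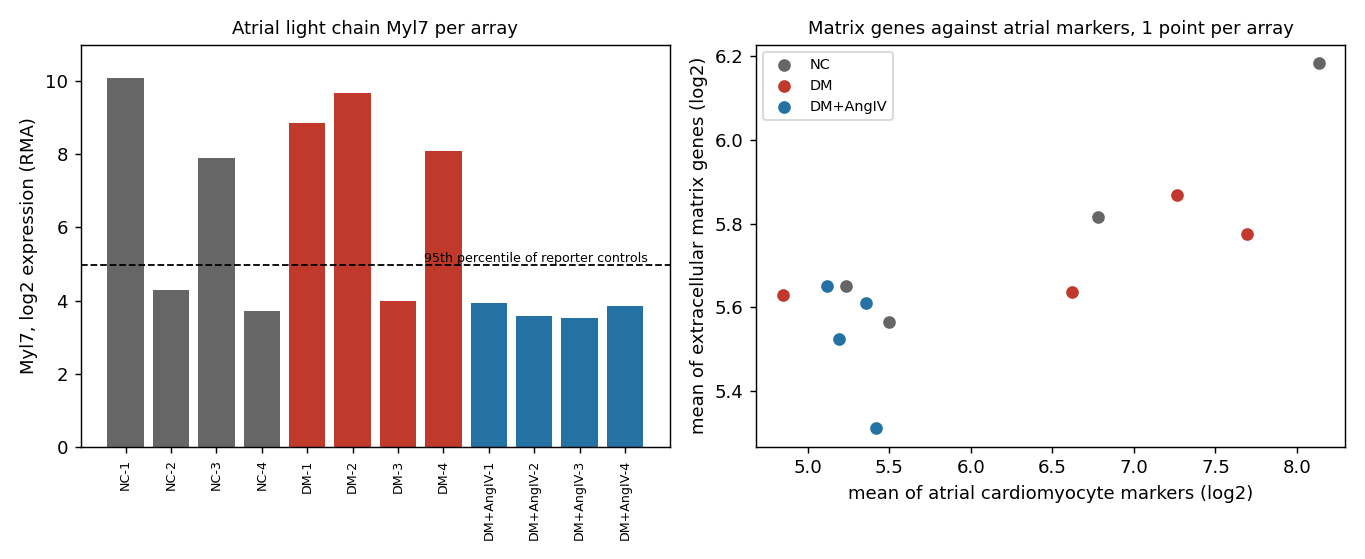
Log2 expression of Myl7 as a bar per array with the background percentile of 4.96 as a dashed line, and the mean log2 expression of the extracellular matrix genes against that of the atrial markers with 1 point per array. Myl7 was above background in 2 NC arrays, 3 DM arrays and 0 DM_AngIV arrays.

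In diabetic mice, compared as DM against NC, 3 genes fell and 0 rose past the threshold. Arntl, which encodes the circadian activator BMAL1, fell from 5.78 ± 0.17 to 4.40 ± 0.13 on the log2 scale (SD, n = 4; limma adjusted p = 0.000752). No DM array was above the background percentile, so Arntl was at least 1.76-fold lower. Abat, the mitochondrial enzyme that breaks down the transmitter GABA, fell by 1.86 ± 0.22 (SE), from 7.33 ± 0.19 to 5.48 ± 0.39 (limma adjusted p = 0.00316). Epha4, a receptor for ephrins, fell by 1.03 ± 0.14, from 6.65 ± 0.11 to 5.62 ± 0.17 (limma adjusted p = 0.00999). Genes of fatty acid oxidation, the glucocorticoid response and the interferon response were higher as groups in DM with the preset correlation, and genes of sterol and fatty acid synthesis were lower.

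Of the 35 gene lists, 9 were called in this comparison with the preset correlation and 0 with an estimated correlation (smallest adjusted p 0.373) or with fry (0.258). Among 38 genes of fatty acid oxidation and PPAR targets, 34 had a positive log2 fold change, 0 passed over all genes and 9 passed, all higher, when adjusted over the list alone. Their mean log2 fold change was 0.35 (camera adjusted p = 1.30e-12, and adjusted p = 0.373 with an estimated correlation). The thioesterases Acot1 and Acot2, which release fatty acids from coenzyme A, had values of 1.61 (limma adjusted p = 0.0985) and 1.07 (0.152). Among 18 glucocorticoid-induced genes, 14 had a positive value and 0 passed over all genes, while 8 passed, all higher, when adjusted over the list alone, with a mean of 0.51 (camera adjusted p = 6.78e-07, and adjusted p = 0.374 with an estimated correlation), which was 0.31 without DM replicate 1. The mean log2 expression of this list was 7.68 and 7.18 in DM replicates 1 and 2, but 6.79 and 6.66 in replicates 3 and 4. In the NC arrays it lay between 6.26 and 6.76. Mt2, a metal-binding metallothionein, had a value of 1.49 (limma adjusted p = 0.0843), and Zbtb16, the transcription factor PLZF, had 1.57 (0.0985). Among 26 interferon response genes, 23 had a positive value, with a mean of 0.25 (camera adjusted p = 3.81e-06, and adjusted p = 0.374 with an estimated correlation), 0 passed over all genes and 2 passed, both higher, when adjusted over the list alone. Ifi204, a DNA sensor, had a value of 0.57 (limma adjusted p = 0.186), and Ifit2, an inhibitor of viral translation, was not above background in either group (0.262).

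The FoxO1 target genes were higher as a list in DM, with 24 of 31 positive values and a mean of 0.25 (camera adjusted p = 4.57e-06, and adjusted p = 0.417 with an estimated correlation). Over all genes 0 of them passed, and 11 higher and 2 lower passed when adjusted over the list alone. The DM arrays differed, with a mean log2 expression of 7.41 and 7.27 in replicates 1 and 2 and of 7.04 and 6.97 in replicates 3 and 4. In the NC arrays it lay between 6.90 and 6.96. The muscle ubiquitin ligase Fbxo32 had a value of 0.51 (limma adjusted p = 0.201) and the mitophagy receptor Bnip3 had 0.55 (0.308). With the atrial covariate the mean log2 fold change of the list was 0.24 (camera adjusted p = 8.30e-06). Without the arrays with atrial marker signal, which leaves 1 DM array, it was 0.14 and the list was not called (camera adjusted p = 0.200). The 24 insulin and FoxO signalling genes had 16 positive values and a mean of 0.10 (camera adjusted p = 0.0401, and adjusted p = 0.432 with an estimated correlation), with 0 passing over all genes or when adjusted over the list alone. Igf1r, a growth factor receptor, had 0.46 (limma adjusted p = 0.302) and the translation inhibitor Eif4ebp1 had 0.46 (0.442). That list was not called without NC replicates 1 or 2, or DM replicates 1 or 2, where its camera adjusted p reached up to 0.189 over the alternatives chosen in advance. It was also not called without the arrays with atrial signal (mean 0.04, camera adjusted p = 0.720).

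Cholesterol and fatty acid synthesis genes were lower as a list in DM, with 19 of 25 negative values and a mean of −0.20 (camera adjusted p = 7.51e-05, and adjusted p = 0.373 with an estimated correlation). Over all genes 0 passed, and 8 passed, all lower, when adjusted over the list alone. The sterol enzymes Msmo1 and Idi1 were not above background in either group (limma adjusted p = 0.128 and 0.205). The list was not called without the genes below the median of all genes (camera adjusted p = 0.0722). Its mean was −0.19 with the atrial covariate (camera adjusted p = 0.000120) and −0.04 without the arrays with atrial signal (0.720). Without NC replicate 3 it was −0.11 (camera adjusted p = 0.0292). Among 18 circadian clock genes 14 had a positive value, with a mean of 0.23 (camera adjusted p = 0.00268, and adjusted p = 0.373 with an estimated correlation). Arntl alone passed over all genes, and 8 higher and 2 lower genes passed when adjusted over the list alone. Per3, a repressor of the clock, had a value of 0.82 (limma adjusted p = 0.0985).

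Cell type markers moved with these groups. All 14 macrophage and monocyte markers had a positive value in DM against NC, with a mean of 0.41 (camera adjusted p = 4.02e-07, and adjusted p = 0.373 with an estimated correlation), and 2 of them, the monocyte genes Ccr2, not above background in either group, and Ly6c2 (0.58), passed when adjusted over the list alone, while 0 passed over all genes. Without DM replicate 1 the mean was 0.25. White and brown adipocyte markers had 10 of 11 negative values and a mean of −0.37 (camera adjusted p = 0.0401, and adjusted p = 0.437 with an estimated correlation), with 0 passing over all genes and 1 when adjusted over the list alone. That 1 was the lipid droplet gene Cidea (0.56), which was higher, against the direction of the list. These 3 markers were named after their values were seen. The adipocyte call was lost without NC replicates 1, 3 or 4, or DM replicates 2 or 4, and without the arrays with atrial signal, where the mean was −0.12 (camera adjusted p = 0.765). Its mean was −0.24 without NC replicate 3 and −0.64 without NC replicate 2, and the call was also lost without the genes of lowest expression (camera adjusted p = 0.157). The atrial list was not called (camera adjusted p = 0.887), and its mean of 0.19 was positive while camera gave its direction as down.

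Genes chosen in advance for the themes of the study and for heart strain did not pass in DM against NC. Foxo1 itself had a log2 fold change of 0.14 ± 0.14 (SE; limma adjusted p = 0.826). The collagens Col1a1 and Col3a1 had values of −0.19 and −0.45 (0.780 and 0.525). Map1lc3b and Becn1, which act in autophagosome formation, had 0.25 and −0.01 (0.546 and 0.991), and the survival gene Bcl2 had 0.17 (0.783). The natriuretic peptides Nppa and Nppb, released by strained heart muscle, had −0.39 and 0.17 (0.949 and 0.954), and the slow myosin Myh7 had 0.55 (0.608). The lists of fibrosis and extracellular matrix genes (camera adjusted p = 0.230), autophagy genes (0.119), pro-apoptotic genes (0.791) and anti-apoptotic genes (0.270) were not called.

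In all, 1745 genes in DM against NC had an unadjusted p below 0.05 where 975 were expected by chance, and 885 genes, 4.54% of all, did not overlap between the groups where chance gives 2.86%. The count of 3 and its direction rested on single arrays, with 6 genes (2 higher), 5 (1 higher) and 30 (19 higher) without NC replicate 1, NC replicate 2 and DM replicate 4, and Epha4 did not pass without NC replicate 3 or DM replicate 2 (highest limma adjusted p 0.0591). All 3 passed with the atrial covariate. Without the arrays with atrial marker signal, which leaves 1 DM array, 0 genes passed while the values of the 3 genes were 0.900 to 1.19 times those over all arrays.

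**Figure D2:**
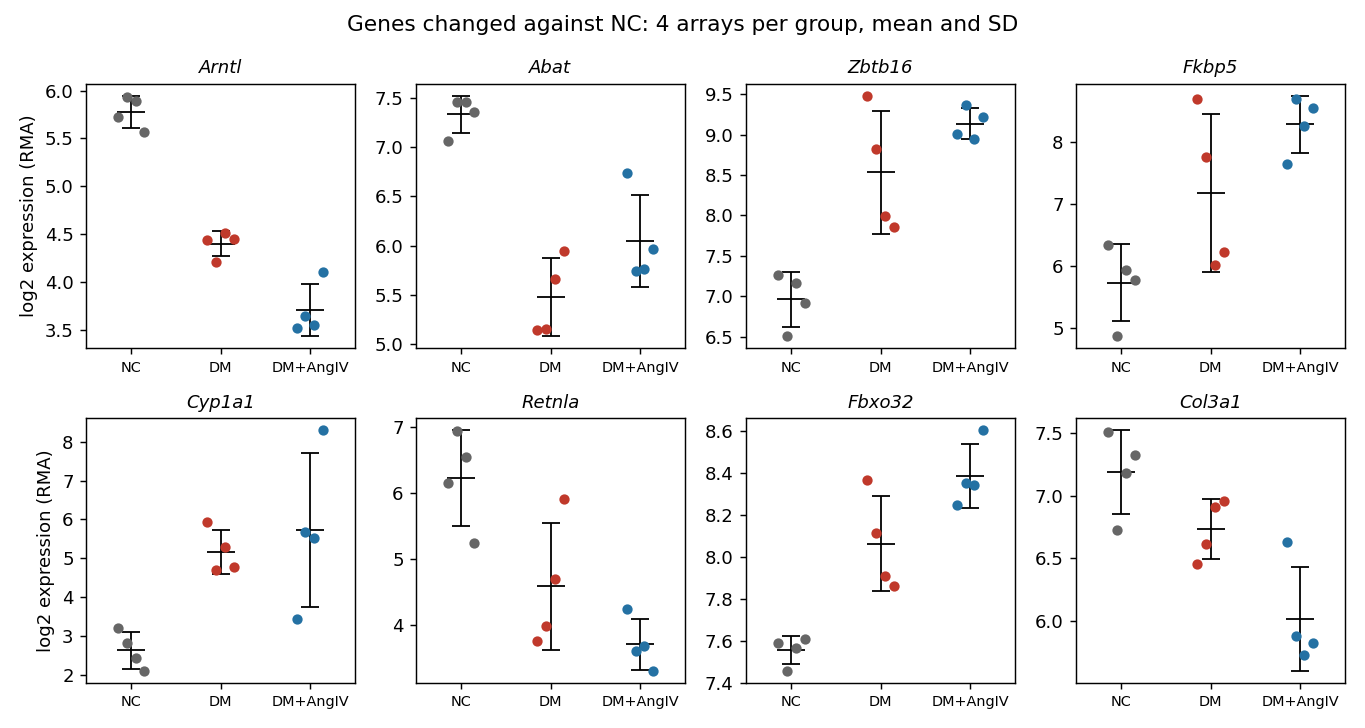
Log2 expression of named genes in each array of NC, DM and DM_AngIV, with group means and SD (n = 4). Arntl lay at 5.78 in NC, and at 4.40 in DM and 3.70 in DM_AngIV, both below the background percentile of 4.96.

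Treatment of diabetic mice, the comparison of DM_AngIV against DM, changed 0 genes past the threshold with limma, where the smallest adjusted p was 0.253. As lists, extracellular matrix genes were lower and genes of glucose use, the interferon response and FoxO1 targets were higher in DM_AngIV with the preset correlation. None of these lists was called with an estimated correlation (smallest adjusted p 0.672) or with fry (0.442). Atrial markers were lower in the same comparison. At an unadjusted p below 0.05 there were 1459 genes where 975 were expected, and 977 genes, 5.01% of all, did not overlap between the groups.

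Among 45 fibrosis and extracellular matrix genes 37 had a negative value in DM_AngIV against DM, with a mean of −0.20 (camera adjusted p = 2.23e-06, and adjusted p = 0.672 with an estimated correlation). None of them passed with limma over all genes or when adjusted over the list alone. Col3a1, a fibrillar collagen, had −0.72 ± 0.20 (SE; limma adjusted p = 0.511) and Loxl1, an enzyme of elastic fibre crosslinking, had −0.53 (0.511). Atrial cardiomyocyte markers moved with this list, with 5 of 7 negative values, a mean of −1.33 (camera adjusted p = 0.0182, and adjusted p = 0.672 with an estimated correlation), 0 passing over all genes and 3 passing, all lower, when adjusted over the list alone. They were Myl7, at least 6.47-fold lower since no DM_AngIV array was above background, Myl4 (−2.40) and Sln (−2.24), named after their values were seen. With the mean of the atrial markers as a covariate, an alternative chosen after seeing the data, the mean of the matrix list was −0.03 (camera adjusted p = 0.380), and without the arrays with atrial signal it was −0.10 (0.255). Without DM_AngIV replicate 4 it was −0.13 (camera adjusted p = 0.00113).

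Genes of glucose uptake, glycolysis and glycogen had 21 of 26 positive values and a mean of 0.14 (camera adjusted p = 0.00108, and adjusted p = 0.672 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, had 0.60 (limma adjusted p = 0.511) and Pygb, a glycogen phosphorylase, had 0.32 (0.600). This list too was not called with the atrial covariate (mean 0.07, camera adjusted p = 0.217) or without the arrays with atrial signal (0.06, 0.527). Interferon response genes had 19 of 26 positive values and a mean of 0.19 (camera adjusted p = 0.00397, and adjusted p = 0.794 with an estimated correlation), but were not called without DM replicate 2 (mean 0.14) or DM_AngIV replicate 1 (0.10; highest adjusted p over the alternatives chosen in advance 0.222) or without the arrays with atrial signal, which leaves 1 DM array (mean 0.11, camera adjusted p = 0.539). With the atrial covariate the list was called (mean 0.20, camera adjusted p = 0.00832). Irf9, a subunit of the interferon-activated transcription factor, was at 5.21 against 4.69 in DM, where no array was above background (limma adjusted p = 0.513), and Tap1, a peptide transporter of antigen presentation, had 0.45 (0.605).

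FoxO1 target genes had 24 of 31 positive values and a mean of 0.10 (camera adjusted p = 0.0182, and adjusted p = 0.817 with an estimated correlation), and were not called without DM replicates 3 or 4 or DM_AngIV replicate 4 (means 0.06, 0.03 and 0.02, highest adjusted p 0.534) or without genes below the median (0.121). The mean was 0.18 without DM replicate 1 and 0.17 without DM_AngIV replicate 1. The stress-induced gene Sesn1 had 0.60 (limma adjusted p = 0.513) and the muscle ubiquitin ligase Trim63 had 0.49 (0.600). Fatty acid oxidation and PPAR target genes had 26 of 38 negative values and a mean of −0.13 (camera adjusted p = 0.0432, and adjusted p = 0.983 with an estimated correlation), a call that was lost without DM replicates 1 or 2 or DM_AngIV replicates 1, 3 or 4 (highest adjusted p 0.896). It was also lost with only the 8 arrays of the 2 groups (camera adjusted p = 0.0754), after centring on the median (0.0522) and with array weights (0.158). The mean was −0.06 without DM replicate 1, −0.19 without DM replicate 4, −0.04 without DM_AngIV replicate 1 and −0.21 without DM_AngIV replicate 2. Cpt2, an enzyme of fatty acid import into mitochondria, had −0.30 (limma adjusted p = 0.605) and Fitm2, a lipid droplet protein, had −0.34 (0.620). Immediate early genes had 16 of 23 negative values and a mean of −0.14 (camera adjusted p = 0.0223, and adjusted p = 0.672 with an estimated correlation), lost without DM replicate 3 or DM_AngIV replicates 1 or 2. Of Fos and Dusp1, both induced within minutes of a stimulus, Fos was not above background in either group (limma adjusted p = 0.600) and Dusp1 had −0.48 (0.513).

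Smooth muscle and pericyte markers had 11 of 11 positive values and a mean of 0.23 (camera adjusted p = 0.0223, and adjusted p = 0.672 with an estimated correlation), and the 14 cardiomyocyte markers had 11 positive values and a mean of 0.09 (camera adjusted p = 0.0432, and adjusted p = 0.817 with an estimated correlation). In the 8 called lists other than the atrial one, 0 members passed over all genes or when adjusted over the list alone, and with the atrial covariate 4 of the 9 lists were called, those of interferon response, FoxO1 target (mean 0.18), immediate early (−0.23) and smooth muscle genes (0.37). The fatty acid oxidation list lost its call at a mean of −0.12 (camera adjusted p = 0.135), close to its −0.13, and the cardiomyocyte list at 0.05 (0.412). Without the arrays with atrial signal 2 of the 9 were called, those of FoxO1 target (mean 0.24) and immediate early genes (−0.27). The smooth muscle call was lost without DM replicate 4 (mean 0.15), DM_AngIV replicate 1 or genes below the median, the cardiomyocyte call without DM replicates 1 or 2 or DM_AngIV replicates 1 or 4, and the atrial call without DM replicates 1 or 2 or DM_AngIV replicate 1.

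Foxo1 had a log2 fold change of −0.12 in DM_AngIV against DM (limma adjusted p = 0.871). Col1a1 had −0.23 (0.767), Map1lc3b 0.15 (0.786), Becn1 0.07 (0.897) and Bcl2 −0.10 (0.897). Nppa, Nppb and Myh7 had 0.04, −0.44 and 0.59 (0.996, 0.827 and 0.677). Nppa is also a member of the atrial marker list, and it did not fall with Myl7. The lists of autophagy genes (camera adjusted p = 0.111), pro-apoptotic genes (0.877) and anti-apoptotic genes (0.573) were not called. Without DM_AngIV replicate 2, 5 genes passed, and without DM_AngIV replicate 4, 1 gene.

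Whether treatment moved genes back toward NC was asked over all genes. With the DM arrays split, the covariance of the log2 fold changes of DM against NC and of DM_AngIV against DM was 0.00525, with a two-sided exact permutation p of 0.443 over 70 relabelings, the smallest possible being 0.0143. A reversal would give a negative value. With all 4 DM arrays in both comparisons the covariance was −0.00707 and the correlation across genes −0.206, where simulated groups without any effect gave −0.0133 and −0.50, so that the observed covariance lay 0.00620 above the simulated one. Genes are not independent replicates.

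**Figure D3:**
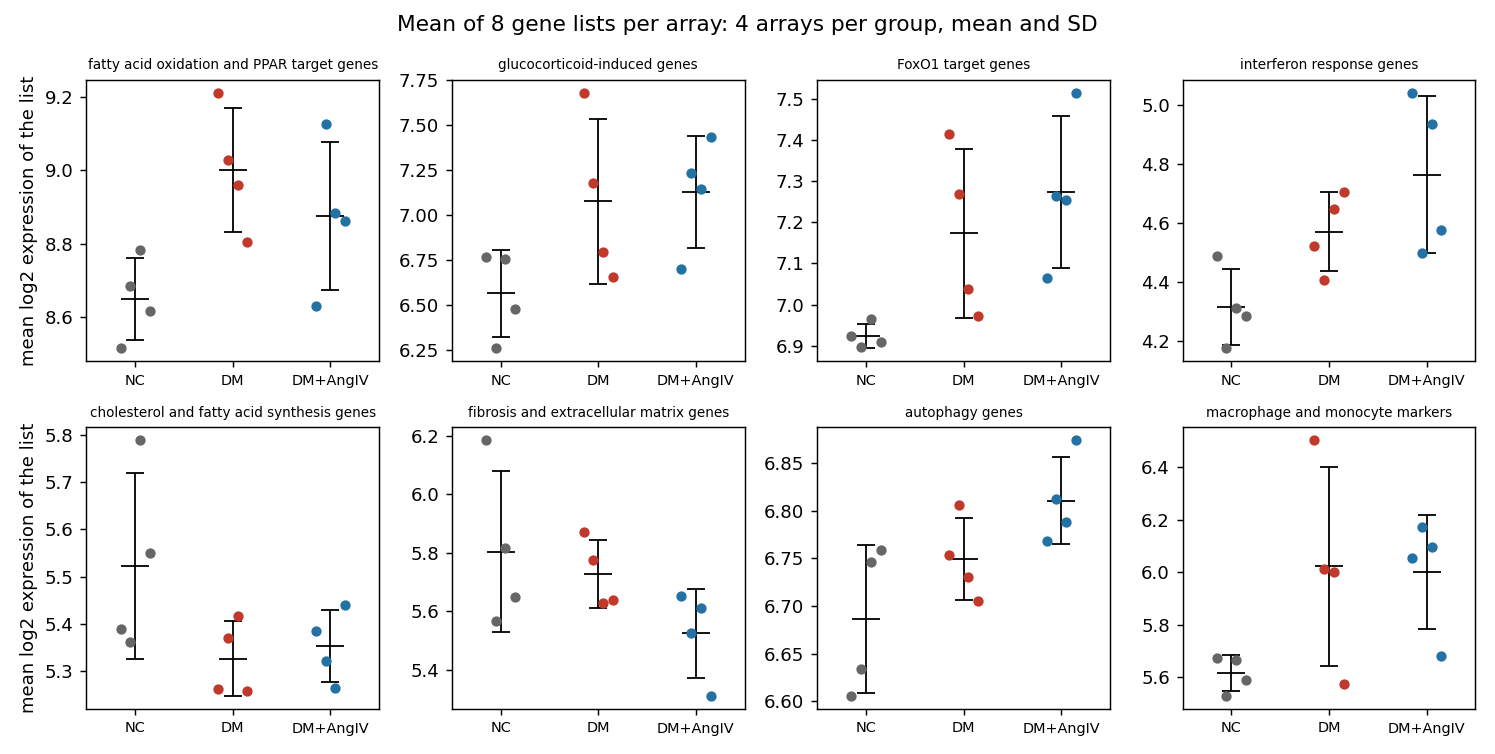
Mean log2 expression of 8 gene lists in each array of NC, DM and DM_AngIV, with group means and SD (n = 4). The mean of the interferon response genes was 4.32 in NC, 4.57 in DM and 4.76 in DM_AngIV.

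Treated diabetic mice differed from NC, the comparison of DM_AngIV against NC, in 198 genes, of which 142 rose and 56 fell. Zbtb16 rose by 2.17 ± 0.28 (SE), a 4.51-fold rise from 6.96 ± 0.34 to 9.13 ± 0.19 (SD, n = 4; limma adjusted p = 0.00317), and the glucocorticoid-induced chaperone Fkbp5 rose by 2.55 ± 0.47, or 5.86-fold (0.0192). Arntl fell to 3.70 ± 0.27 (limma adjusted p = 2.53e-06) and Retnla, a product of alternatively activated macrophages, fell from 6.22 ± 0.73 to 3.71 ± 0.39 (0.0102). No DM_AngIV array was above background for either, so they were at least 1.76-fold and at least 2.40-fold lower. Interferon response genes and FoxO1 targets were higher as lists with the preset correlation, and extracellular matrix genes were lower, with adjusted p = 0.366, 0.390 and 0.390 with an estimated correlation.

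The other large rises were in Cyp1a1, a target of the aryl hydrocarbon receptor, from 2.63 ± 0.47 to 5.73 ± 1.99 (SD, n = 4; limma adjusted p = 0.0380), Etv5, an ETS transcription factor, by 1.78 (0.0102), Rasgef1b, an exchange factor of Ras proteins, by 1.48 (0.0128), and Fmo2, a flavin monooxygenase, by 1.46 (0.0281). Cyp1a1 was above background on 0 NC arrays and 3 DM_AngIV arrays, so that it was at least 1.71-fold higher, and Etv5 and Rasgef1b were above it on 1 NC array each. Cyp1a1 ranged from 3.43 to 8.30 in the 4 DM_AngIV arrays and from 2.10 to 3.19 in NC, and in DM it lay between 4.70 and 5.93. Its lower bound rests on the array at 8.30, without which the DM_AngIV mean lay below the background percentile. The other large falls were in Myl1, a myosin light chain of fast skeletal muscle, by 1.46 (limma adjusted p = 0.00130), Slc41a3, a magnesium transporter, by 1.44 (0.00130), Klhdc8a, a kelch domain protein, from 5.81 to 4.43 (0.00699), at least 1.80-fold as no DM_AngIV array was above background, and Abat by 1.28 (0.0126). Of the 25 called genes that the rule names, 14 passed in all 8 fits with 1 array left out and 21 passed with the atrial covariate. Without the arrays with atrial signal, which leaves NC replicates 2 and 4 as the only NC arrays, 9 passed. All 25 values kept their direction in that fit, at 0.822 to 1.20 times those over all arrays. Cyp1a1 did not pass without any of the 4 NC arrays or without DM_AngIV replicates 2 or 3 (highest limma adjusted p 0.0928), Fkbp5 without NC replicate 2 or DM_AngIV replicates 2, 3 or 4 (0.0680), and Fmo2 without NC replicates 2, 3 or 4 or DM_AngIV replicates 1, 3 or 4 (0.0923).

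Among 26 interferon response genes 24 had a positive value in DM_AngIV against NC, 2 rose over all genes and 13 when adjusted over the list alone, with a mean of 0.45 (camera adjusted p = 4.37e-10, and adjusted p = 0.366 with an estimated correlation). Ifit2 rose from 4.06 to 5.14 (limma adjusted p = 0.0102), at least 1.13-fold as no NC array and 3 DM_AngIV arrays were above background, and Tap1 rose by 0.69 ± 0.15 (0.0446). Tap1 passed in 1 of 8 fits with 1 array left out, the fit without DM_AngIV replicate 2 (highest limma adjusted p of the others 0.133). Among 31 FoxO1 targets 4 rose over all genes, 16 rose and 1 fell when adjusted over the list alone, and the mean was 0.35 (camera adjusted p = 2.62e-08, and adjusted p = 0.390 with an estimated correlation). They were Fbxo32, by 0.83 ± 0.12 (limma adjusted p = 0.00699), Sesn1, by 1.15 ± 0.18 (0.00834), the transcriptional coregulator Cited2, by 1.21 (0.0126), and Eif4ebp1, by 0.79 (0.0396). Cited2 and Eif4ebp1 stand outside the naming rule here and are given because they complete the count. Eif4ebp1 passed only without DM_AngIV replicate 1 among the 8 fits with 1 array left out (highest limma adjusted p 0.118).

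Of the 24 insulin and FoxO signalling genes 3 rose over all genes and 6 when adjusted over the list alone, with a mean of 0.18 (camera adjusted p = 0.00129, and adjusted p = 0.390 with an estimated correlation). They were Pik3r1, the regulatory subunit of phosphoinositide 3-kinase, by 0.87 ± 0.17 (limma adjusted p = 0.0218), the transcription factor Foxo3, by 0.55 ± 0.11 (0.0236), and again Eif4ebp1, by 0.79 (0.0396). Pik3r1 did not pass without NC replicates 2 or 4 or DM_AngIV replicates 2, 3 or 4 (highest limma adjusted p 0.0753), and Foxo3 passed only without DM_AngIV replicate 1 among the 8 such fits (0.0881). Foxo1 had a value of 0.02 ± 0.14 (limma adjusted p = 0.965).

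Among 18 circadian clock genes 5 rose and 2 fell over all genes, and 10 rose and 3 fell when adjusted over the list alone, with a mean of 0.30 (camera adjusted p = 0.000162, and adjusted p = 0.317 with an estimated correlation). The repressor Per2 rose from 4.61 to 5.73 (limma adjusted p = 0.00130), at least 1.71-fold as no NC array was above background. Named to complete the count, Per3 rose by 1.19 (limma adjusted p = 0.00317), the repressor Nr1d2 by 0.76 (0.00834), the output factor Tef by at least 1.23-fold over NC arrays not above background (0.0128) and the repressor Cry2 by 0.61 (0.0446), and beside Arntl its partner Clock fell by 0.66 (0.00951). Tef did not pass without DM_AngIV replicate 3. Cry2 passed in 0 of the 8 fits with 1 array left out (highest limma adjusted p 0.110). Among 18 glucocorticoid-induced genes 4 rose and 1 fell over all genes, and 9 rose and 1 fell when adjusted over the list alone, with a mean of 0.56 (camera adjusted p = 6.22e-05, and adjusted p = 0.390 with an estimated correlation). Besides Zbtb16 and Fkbp5, the rises were in the metallothioneins Mt1, by 0.70 (limma adjusted p = 0.0236; named to complete the count), and Mt2, by 1.21 (0.0264). Mt1 did not pass without NC replicates 1, 3 or 4 or DM_AngIV replicates 2 or 4 (highest limma adjusted p 0.0806). Mt2 passed only without NC replicate 1 or DM_AngIV replicate 2 (0.0868). The 1 that fell was Dusp1, by 0.71 ± 0.14 (limma adjusted p = 0.0236), a phosphatase that inactivates MAP kinases.

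**Figure D4:**
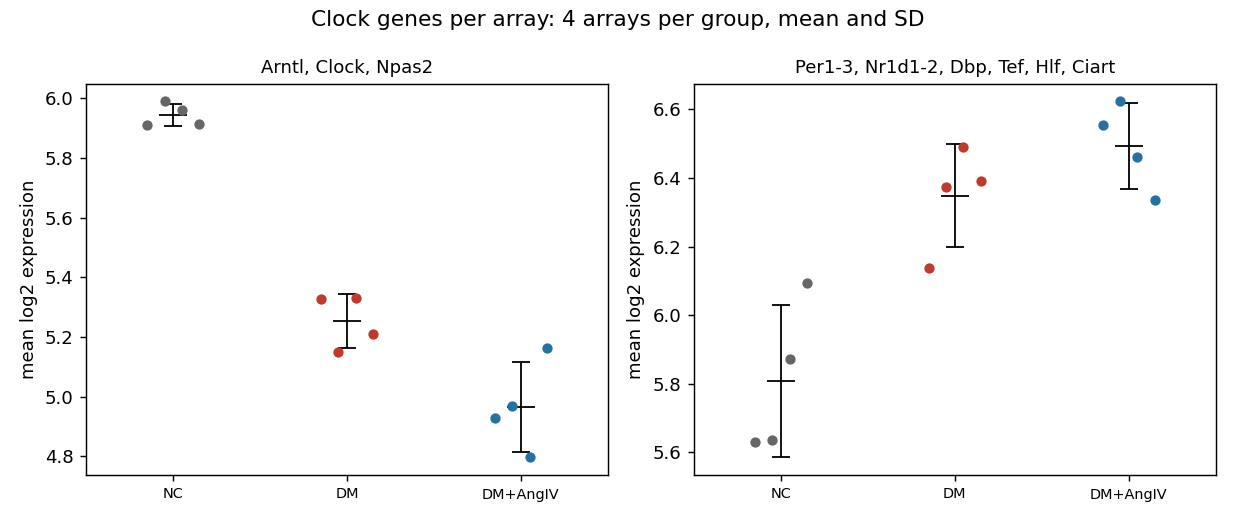
Mean log2 expression of Arntl, Clock and Npas2 and of 9 other clock genes (Per, Nr1d, Dbp, Tef, Hlf and Ciart) in each array of the 3 groups, with group means and SD (n = 4). The mean of the 9 genes minus that of the 3 was −0.14 in NC, 1.09 in DM and 1.53 in DM_AngIV.

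Fibrosis and extracellular matrix genes had 35 of 45 negative values in DM_AngIV against NC, with 3 falls over all genes, 6 falls when adjusted over the list alone and a mean of −0.28 (camera adjusted p = 9.80e-07, and adjusted p = 0.390 with an estimated correlation). Col3a1 fell by 1.17 ± 0.20 (limma adjusted p = 0.0128), Col6a2, a collagen of the cell border, by 0.63 ± 0.12 (0.0207) and the collagen chaperone Serpinh1, named to complete the count, by 0.73 (0.0225). Col6a2 did not pass without NC replicates 1, 2 or 4 or DM_AngIV replicates 3 or 4 (highest limma adjusted p 0.0669). Serpinh1 did not pass without NC replicates 3 or 4 or DM_AngIV replicates 2, 3 or 4 (0.0813). Col1a1 had −0.42 (0.226). All 7 atrial markers had negative values beside it, with a mean of −1.14 (camera adjusted p = 0.0142, and adjusted p = 0.390 with an estimated correlation) and 0 passing over all genes, a call that was lost without NC replicate 1 (mean −0.57) or 3. The mean of the matrix list was −0.13 with the atrial covariate (camera adjusted p = 0.0396) and −0.08 without the arrays with atrial signal (0.310), and it was −0.15 without NC replicate 1 (0.00453). With the covariate Col3a1, Col6a2 and Serpinh1 kept values of −1.16, −0.66 and −0.78 (limma adjusted p = 0.0284, 0.0312 and 0.0338). Without the arrays with atrial signal, which leaves NC replicates 2 and 4, their values were −1.01, −0.67 and −0.73, and they did not pass.

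Fatty acid oxidation and PPAR target genes had 31 of 38 positive values, 2 rises over all genes and 2 when adjusted over the list alone, with a mean of 0.23 (camera adjusted p = 3.64e-05, and adjusted p = 0.506 with an estimated correlation), which was 0.14 without DM_AngIV replicate 2. Pnpla2, the triglyceride lipase of lipid droplets, rose by 0.75 ± 0.13 (limma adjusted p = 0.0137) and Cpt1a, which admits fatty acids to mitochondria, by 0.86 ± 0.19 (0.0446). Pnpla2 did not pass without DM_AngIV replicate 4 (0.0525), and Cpt1a passed only without DM_AngIV replicate 1 among the 8 such fits (highest limma adjusted p 0.129). Cholesterol and fatty acid synthesis genes had 17 of 25 negative values, 0 passing over all genes, 1 rise and 5 falls when adjusted over the list alone and a mean of −0.17 (camera adjusted p = 0.00790, and adjusted p = 0.390 with an estimated correlation), a call lost without NC replicate 3 (mean −0.08), without genes below the median (−0.12) and without the arrays with atrial signal (−0.10; camera adjusted p = 0.212, 0.0787 and 0.202). Msmo1 was not above background in either group (limma adjusted p = 0.101) and Srebf2, the master regulator of sterol synthesis, had −0.35 (0.0897). The 5 ketone body metabolism genes had 4 negative values and a mean of −0.44 (camera adjusted p = 0.0322, and adjusted p = 0.390 with an estimated correlation), with 0 passing over all genes. That call was lost without NC replicates 3 or 4 or DM_AngIV replicates 2, 3 or 4, and Bdh1, an enzyme of ketone use, had −1.43 (limma adjusted p = 0.113) and the ketone transporter Slc16a7 was at 4.83 against 5.18 in NC, with no DM_AngIV array above background (0.322).

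Autophagy genes had 24 of 37 positive values, 0 passing over all genes and 8 rises when adjusted over the list alone, with a mean of 0.12 (camera adjusted p = 0.00668, and adjusted p = 0.390 with an estimated correlation). The call was lost without genes below the median, at a mean of 0.13 (camera adjusted p = 0.0621). Calcoco1 and Sqstm1, both cargo receptors, had 0.47 (limma adjusted p = 0.0637) and 0.41 (0.102), Map1lc3b had 0.40 (0.114) and Becn1 had 0.06 (0.839). Pro-apoptotic genes were not called (camera adjusted p = 0.566), and neither were anti-apoptotic genes (0.112), of which 1 of 14 rose over all genes and 2 when adjusted over the list alone. The rise over all genes was in Bcl2l1, which blocks mitochondrial apoptosis, by 1.27 (limma adjusted p = 0.0245), lost without NC replicates 2 or 4 or DM_AngIV replicates 2, 3 or 4 (highest 0.0824). Bcl2 had 0.06 (limma adjusted p = 0.888). Of the other lists without a call, that of endoplasmic reticulum stress genes (camera adjusted p = 0.672) held 1 rise over all genes, in Herpud1, a gene of protein degradation at that organelle, by 1.09 (limma adjusted p = 0.00834), and that of oxidative stress and antioxidant genes (0.256) held 2, in Mt1 and Mt2. Immediate early genes had 18 of 23 negative values, 1 rise and 1 fall over all genes, and 3 rises and 7 falls when adjusted over the list alone, with a mean of −0.21 (camera adjusted p = 0.00809, and adjusted p = 0.366 with an estimated correlation). The rise was in Ier3, a stress-induced survival gene, by 0.74 ± 0.16 (limma adjusted p = 0.0358), and the fall was that of Dusp1. Among the 8 fits with 1 array left out, Ier3 passed only without NC replicate 3 or 4 and Dusp1 only without DM_AngIV replicate 2 (highest limma adjusted p 0.118 and 0.0813).

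Among cell type markers, all 14 of macrophages and monocytes had positive values in DM_AngIV against NC, with 0 passing over all genes, 3 rises when adjusted over the list alone and a mean of 0.39 (camera adjusted p = 0.000139, and adjusted p = 0.390 with an estimated correlation). Endothelial cell markers had 8 of 11 positive values and a mean of 0.19 (camera adjusted p = 0.0438, and adjusted p = 0.568 with an estimated correlation), with 1 rise over all genes, in Ly6c1 (0.86, limma adjusted p = 0.0446), which passed in 0 of the 8 fits with 1 array left out (highest 0.124). White and brown adipocyte markers had 10 of 11 negative values and a mean of −0.42 (camera adjusted p = 0.0210, and adjusted p = 0.390 with an estimated correlation), with 0 passing over all genes. The endothelial call was lost without NC replicates 1, 2 or 3 or DM_AngIV replicates 1 or 3, and the adipocyte call without NC replicates 1, 3 or 4 or DM_AngIV replicate 2. The adipocyte mean was −0.69 without NC replicate 2. Both calls were lost with the atrial covariate at means of 0.20 and −0.35 against 0.19 and −0.42 (camera adjusted p = 0.0796 and 0.0897), and without the arrays with atrial signal (means 0.17 and −0.18, camera adjusted p = 0.0797 and 0.339). Nppa, Nppb and Myh7 had −0.35, −0.27 and 1.14 (limma adjusted p = 0.904, 0.825 and 0.0675).

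In DM_AngIV against NC, 2855 genes had an unadjusted p below 0.05, and 1918 genes, 9.83% of all, did not overlap between the groups where chance gives 2.86%. The count of 198 was 95, 81 and 101 without NC replicates 1, 2 and 4 and 97, 82 and 84 without DM_AngIV replicates 2, 3 and 4. It was 50 without the arrays with atrial signal, which leaves NC replicates 2 and 4, and 37 of these genes were among the 198. No list was called with an estimated correlation (smallest adjusted p 0.317) or with fry (0.0516). The 3 genes lower in DM than in NC were also lower in DM_AngIV than in NC, where independent lists of these sizes would share 0.00861. Simulated groups without an effect, compared against the same simulated NC arrays, shared 0 called genes since few were called, but the 3 and 198 genes with the smallest p shared 1.36 on average and up to 3 in 100 simulations. An overlap of 3 is therefore within what common NC arrays alone can give. With the NC arrays split between the comparisons, DM against NC called 0 to 7 genes, of which 0 to 1 were shared over the 6 splits. In every split with a call in DM against NC 1 gene was shared, where independent lists would share at most 0.00702. Some sharing thus remained without common NC arrays.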

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

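The tests with marker means as covariates, the within-group tests and the distance between the sets of clock genes were chosen only after the results were seen, while the splits of the arrays were planned. A gap of 1 array from the other 3 of its group was looked for in 276 groups of 4 values over 57 genes and 35 lists, and 10 were found where chance gives 13.8.

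In DM_AngIV replicate 1, the ketone enzyme Bdh1 stood at 7.56 against 5.86 to 5.93 in the other arrays of the group, the mean of the ketone body metabolism genes at 8.29 against 7.78 to 7.83, and Col3a1 at 6.63 against 5.73 to 5.88. In DM_AngIV replicate 2, Cpt2 stood at 7.98 against 7.75 to 7.77, Dusp1 at 7.93 against 7.37 to 7.46, and Foxo1 at 5.25 against 5.72 to 5.73. Irf9 was at 4.95 in DM replicate 1 against 4.59 to 4.61. In NC replicate 2, Loxl1 was at 6.02 against 6.18 to 6.20 and Sqstm1 at 9.09 against 9.28 to 9.30, and in NC replicate 3 Slc16a7 was at 5.65 against 4.98 to 5.05. Among gene probe sets without a gene name here, outside the measurement the comparisons use, 18 passed in DM_AngIV against NC, 15 higher and 3 lower, and 0 passed in the other comparisons.

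Extracellular matrix genes had a lower mean in DM_AngIV than in DM, and the atrial markers moved with them. The difference of −0.203 had an SE of 0.136 between arrays, so chance stays open. With the atrial marker mean as a covariate the difference went from −0.203 to −0.0271 (SE 0.116). Pooled over the groups, the matrix mean followed the atrial mean within groups (exact permutation p = 0.0182). NC replicate 1 was the highest array in both means (8.13 and 6.18). In DM_AngIV the relation did not hold, as replicate 4 had the highest atrial mean (5.42) and the lowest matrix mean (5.31). Atrial tissue in some arrays is a candidate explanation of the difference in this list, but the atrial marker Nppa was not lower in DM_AngIV. With 7 fibroblast markers outside the list as a covariate the difference was −0.13 (SE 0.10; within-group exact permutation p = 0.00702), so a smaller share of fibroblasts cannot be told apart from lower matrix expression. An effect of angiotensin IV stays among the open explanations and cannot be separated from the absence of atrial signal in its 4 arrays.

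The clock genes differed as a list between NC and DM with the preset correlation, but not with an estimated correlation (adjusted p = 0.373), and 1 of 18, Arntl, passed over all genes. Fry for changes in either direction called this list (adjusted p = 3.73e-06), as 1 of 9 lists in DM against NC. In that form fry called 0 lists in DM_AngIV against DM and 17 in DM_AngIV against NC. In sets chosen after the values were seen, the mean of 9 Per, Nr1d, Dbp, Tef, Hlf and Ciart genes minus that of Arntl, Clock and Npas2 was higher in DM by 1.23, and by 0.78 with values below the background percentile set to it. With the atrial marker mean as a covariate these changes were 1.24 (SE 0.16; within-group exact permutation p = 0.377) and 0.80 (SE 0.09), which argues against atrial tissue as its source. Hearts collected at different times of day could give the same difference, and the test of it, a change of 1.23 with a within-group exact permutation p of 0.302, does not decide, since the hour of sampling is not given in the sources used here. Diabetes itself stays open.

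Interferon response genes had a higher mean in DM_AngIV than in DM, by 0.19 (SE 0.13 between arrays), so chance stays open. With the macrophage and monocyte marker mean as a covariate the difference was 0.19 (SE 0.14; within-group exact permutation p = 0.897). That mean was 6.02 ± 0.38 in DM and 6.00 ± 0.22 in DM_AngIV, but its difference of −0.02 has a 95% interval from −0.43 to 0.39, so more macrophages stay open. With the atrial marker mean as a covariate the difference was 0.20 (SE 0.16; exact permutation p = 0.870), and the list was still called (camera adjusted p = 0.00832), so the covariate did not reduce it, but the spread between arrays leaves atrial tissue open too. An effect of angiotensin IV also stays open.

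Chance was tested with the 35 splits of the 8 arrays in each comparison. For DM against NC, 2 of 35 splits gave as many genes as the real 3, and the highest other split gave 3, so chance was not excluded. That other split set NC replicates 1 and 3 with DM replicates 1 and 2, which are 4 of the 5 arrays with atrial signal. Its lists were not distinguished from chance either, since 16 of 35 splits gave as many as the real 9 and the highest other gave 15. For DM_AngIV against DM the real count of genes was 0, which 35 of 35 splits reach by construction (highest other 1), so that this count tests nothing. For its lists, 5 of 35 splits gave as many as the real 9, with 11 as the highest other, and chance was not excluded. For DM_AngIV against NC, 1 of 35 splits, the real one, gave 198 genes and the highest other gave 0, which argues against chance for the genes. With the preset correlation 1 of 35, again the real one, gave 15 lists and the highest other gave 12. That margin is small, and 0 lists were called with an estimated correlation (smallest adjusted p 0.317) or with fry (0.0516). The smallest p of an exact permutation test with these 35 splits is 0.0286. It was not adjusted over the comparisons, so chance was not excluded.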

How the results depend on the processing

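The atrial covariate and the omission of arrays with atrial signal were chosen after seeing the data, and the cause of each change below was not tested except where fewer arrays or a looser threshold make it. In DM against NC the count of 3 genes (0 higher) became 17 (11 higher) at an adjusted p below 0.1, 167 at an unadjusted p with a fold change of at least 1.5, 20 (14 higher) without genes below the median, 28 (16 higher) with an intensity trend and robust estimation, 2 to 30 (19 higher) with 1 array left out, 5 with the atrial covariate and 0 without atrial arrays, where the lone DM array is assumed to vary like the other groups. The 9 lists became 0 with an estimated correlation, 0 with fry, 14 with trend and robust estimation, 7 to 14 with 1 array left out and 5 without atrial arrays. In DM_AngIV against DM the 0 genes became 74 at an unadjusted p with a 1.5-fold change and 0 to 5 with 1 array left out. Its 9 lists became 0 with an estimated correlation, 0 with fry and 3 to 10 with 1 array left out (3 without DM_AngIV replicate 1). With the covariate 5 lists were called, 4 of them among the 9, and without atrial arrays 3 were, 2 of them among the 9. In DM_AngIV against NC the 198 genes became 509 at an adjusted p below 0.1, 367 at an unadjusted p with a 1.5-fold change, 492 without genes below the median (173 shared), 514 with trend and robust estimation (190 shared), 81 to 167 with 1 array left out and 50 without atrial arrays, and stayed within 1.5 times in the other alternatives run except the replicate block, with 197 after quantile scaling and 187 after centring. The 15 lists became 0 with an estimated correlation, 0 with fry and 10 to 15 with 1 array left out. The covariance was negative only with all 4 DM arrays in both comparisons (−0.00707), by the construction of that alternative, and the covariance over called genes was not run, since the split DM arrays called between 0 and 66 genes. For named genes no called value changed sign, and 1299 planned values kept their side of the threshold, 79 fell below it and 24 rose past it, while 21 that had not passed changed sign. Only called genes could fall below it, 3 in DM against NC and 25 in DM_AngIV against NC, and 77 of the 79 losses were in the latter. Most of the 1299 belong to genes that were not called, with 336 in DM_AngIV against DM, where no gene passed. Signal over background limits what can be seen, since at most 45.6% of genes were above the background percentile.

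Replicate numbers shared by the groups did not pair the arrays. Residuals of the 12 same-numbered pairs correlated between −0.0980 and 0.171, 1 of them above 0.1, and 2 of 12 arrays correlated best with their own number. With the replicate block, 115 genes passed in DM_AngIV against NC (99 shared with the 198) and the covariance was 0.00154 (exact permutation p = 0.843).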

Other observations

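The genes in the first paragraph were chosen after their values were seen, while the comparison of DM with NC in the second was planned before its result was seen.

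The following 7 genes passed in DM_AngIV against NC, and were not tested as a group. The class I heavy chains H2-D1 and H2-K1 rose by 0.74 (limma adjusted p = 0.0128) and 0.77 (0.0126), and B2m, their light chain, rose by 0.58 (0.0236). The GTPases Irgm1 and Igtp, which act on vacuoles of intracellular microbes, rose by 1.06 (limma adjusted p = 0.00834) and 0.98 (0.0372). Cd274, the checkpoint ligand PD-L1, rose at least 1.40-fold over NC arrays not above background (limma adjusted p = 0.0331), and Trim21, an intracellular antibody receptor, passed (0.0192) with neither group above background. H2-D1, H2-K1 and Irgm1 passed in all 8 fits with 1 array left out. B2m did not pass without NC replicates 1, 2 or 4 or DM_AngIV replicates 1 or 3 (highest limma adjusted p 0.0892), and Trim21 without NC replicate 2 or DM_AngIV replicates 3 or 4 (0.0715). Igtp and Cd274 passed only without DM_AngIV replicate 2 (highest limma adjusted p 0.103 and 0.0968). With the atrial covariate Igtp and Cd274 did not pass (limma adjusted p = 0.0808 and 0.0521). Without the arrays with atrial signal the 7 genes did not pass, while H2-D1, H2-K1 and Irgm1 had values of 0.89, 0.87 and 1.11. Against DM, Irgm1 had a value of 0.85 (0.253) and Igtp 1.24 (0.253), which did not pass.

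Few genes passed in DM against NC and 198 in DM_AngIV against NC, and a hypothesis is that DM had moved the same genes by less than the threshold. Genes were called in DM_AngIV against 2 of the NC arrays, and their direction in DM was then read against the other 2. Over the 6 splits of the NC arrays, 218 of 234 calls, or 93.2%, had the same direction in DM, with 88.2% to 97.7% per split, where 55.3% of all genes did. This is consistent with a displacement already present in DM, and it does not show how much of it angiotensin IV added.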
